A study of Homo sapiens with 12 samples.

How the data were processed

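Total RNA of 12 samples of RMG1 cells was extracted with Trizol and an RNeasy kit, made into libraries with the ScriptSeq Complete Gold kit and sequenced in pairs of 75 bp reads on a NextSeq 500, per the labels. The authors deposited 1 table of whole-number counts for 57736 Ensembl genes, not scaled between libraries. The labels name RSEM 1.2.3, DESeq2 and the genome build hg19 without saying in which order they were used, so the deposited counts may be rounded RSEM estimates. The aligner, the annotation release and the strand of counting are not stated. Reads were not analysed here.

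Samples were grouped by genotype and treatment from their titles, with 3 libraries in each of 4 groups. Gene names came from a table made for GENCODE release 29, which belongs to another build than the counts, so chromosome names and gene order were used and no coordinates are given. Of the gene IDs 51959 had a name and 5777 had none. Of the tested genes 414 had none, and unnamed IDs held 1.29% to 1.59% of the counts of a library.

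The choices of this paragraph were made before the data were examined. Counts were analysed in R 4.3.3 with edgeR 4.0.16, with TMM scaling, the filterByExpr filter (minimum count 10, minimum total 15), a mean for each of the 4 groups and robust quasi-likelihood F-tests with 8 residual degrees of freedom. The 5 comparisons were tunicamycin against control in WT and in KO cells, KO against WT under control condition and under tunicamycin, and the difference between the 2 tunicamycin responses (the interaction). A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The fit covered 13588 genes, with a common dispersion of 0.0706, which is a biological coefficient of variation of 0.266. SE is the standard error of a log2 fold change, and a fold change of a group with no counts is given as a bound against 3 counts in each library of the group (the mean of those floors in CPM). A ratio to a group with 1 to 3 counts is given with a 95% counting interval (exact binomial, Clopper-Pearson).

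The genes the text names follow a rule set with those choices. ARID1A comes first. For each comparison the rule takes the 10 genes with the largest rise and the 10 with the largest fall (5 and 5 for the interaction) among called genes with at least 5 CPM in the higher group and groups that do not overlap. It adds the sensors and transducers of the unfolded protein response, and up to 4 members with the smallest adjusted p of each list described. Fewer are named where space was short, always from the top, and the results of some genes that the rule takes are not reported here. Genes are also named together by their place on a chromosome, a grouping chosen after their values were seen. The other genes of the interaction are named because all 17 had to be given.

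There were 27 gene lists with 583 entries, of which 578 are in the table. They were tested with camera of limma 3.58.1 at its preset correlation of 0.01, and again with a correlation estimated for each list and with fry. The median, the mean and the test differed in sign in 30 of 135 pairs of list and comparison, and camera called 0 of these 30. The lists cover the sensors, the targets of PERK and ATF4, of ATF6 and of IRE1 and XBP1, ER-associated degradation, N-glycosylation, IRE1-dependent decay, ER-stress apoptosis, ER-to-Golgi transport, aminoacyl-tRNA synthetases, serine and one-carbon enzymes, cholesterol, NRF2, p53, cell cycle, ribosomal proteins, oxidative phosphorylation, hypoxia, autophagy, interferon, NF-kB, SWI/SNF, genes linked to ARID1A, epithelial, mesenchymal and clear cell carcinoma markers, and markers of other cell types.

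Alternatives were RLE and upper-quartile scaling, no filter, a filter of at least 50 counts in 3 libraries, DESeq2 1.42.0, limma-voom, a fit of the 2 groups compared, a replicate block, an adjusted p under 0.01, a test against a fold change of 1.5, and leaving out each library. A fit with the within-group axis as a covariate and a fit of 2 libraries per group were chosen after the data were seen. Windows of 50 neighbouring genes with a mean of at least 10 CPM were compared with 1000 random gene orders, leaving out the Y chromosome.

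The tests were run on simulated data. For the 5 comparisons in the order given 53%, 33%, 37%, 40.0% and 11% of 2-fold changes and 73%, 72%, 69%, 67% and 55% of 4-fold changes were recovered, with 5.3%, 0%, 6.2%, 0.9% and 9.6% false calls. In simulated counts of tunicamycin in KO cells limma-voom recovered 65% of the 4-fold changes with 4.3% false calls, and DESeq2 79% with 12.8%. A chromosome of 7 windows shifted by 0.4 (log2) had 2 windows beyond the limit, one shifted by 0.7 had 7, and one with no shift had 0. The shift of 0.7 was added after the shift of 0.4 was seen to move so few.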

Results

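RNA was sequenced from RMG1 cells, an established line of ovarian clear cell carcinoma, in 12 libraries. The cells were ARID1A wild type (WT) or ARID1A knockout (KO), and each genotype was kept under a control condition or treated with tunicamycin, with 3 libraries in each of the 4 groups. ARID1A is a subunit of the SWI/SNF chromatin remodelling complex. Tunicamycin blocks N-linked glycosylation, so that misfolded proteins collect in the endoplasmic reticulum (ER) and the unfolded protein response is set off. The series title places the question in the IRE1α/XBP1 branch of that response in ARID1A-mutant ovarian cancers. The labels give no dose, time or route of knockout and do not say whether the replicates were separate cultures, so the p-values measure the spread between these samples only.

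The WT control libraries held 5708732, 5276323 and 6094015 counts, and the WT tunicamycin libraries 4970562, 5761722 and 5698674. The KO control libraries held 5238805, 6168953 and 5754600 counts, and the KO tunicamycin libraries 5858914, 5164132 and 6238765. Levels are given as CPM, the counts of a gene scaled to a common library total. At this depth 1 CPM stood for 4.82 to 6.47 counts, and 3 counts, the limit that a count of 0 allows, for 0.464 to 0.623 CPM in a library. Values after ± are standard deviations (SD, n = 3 libraries), and log2 fold changes come from the fit of 13588 tested genes. On the principal components of all libraries the genotypes separated along the first component (32.2% of the variance) and the treatments along the second (16.8%).

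**Figure D1:**
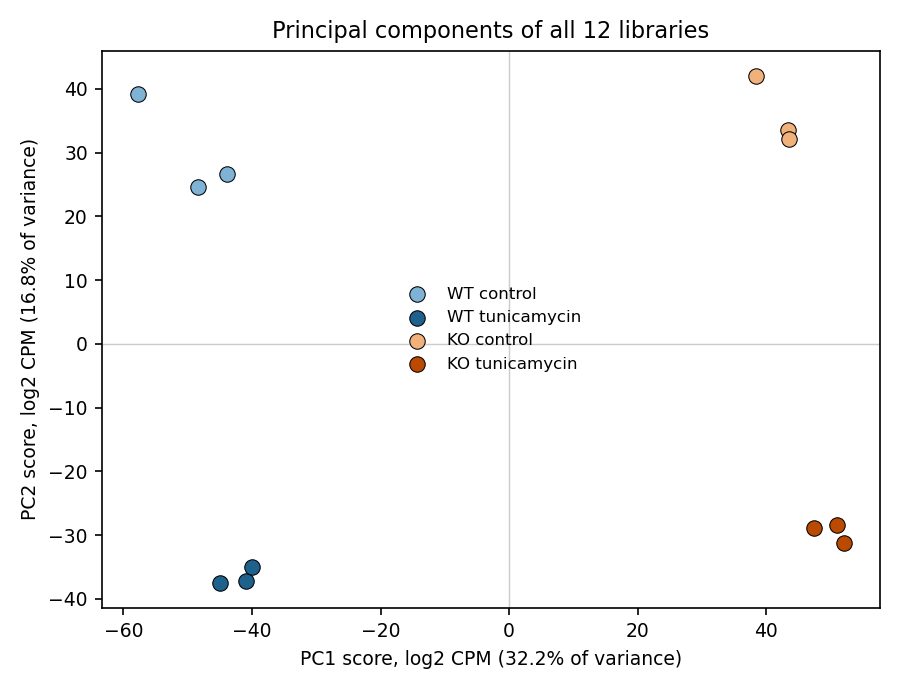
Scores of the 12 libraries on the first (x axis) and second (y axis) principal components of log2 CPM; each point is a library, coloured by group. The first component (32.2% of the variance) separates KO from WT and the second (16.8%) separates control from tunicamycin.

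ARID1A (ENSG00000117713) stood at 60.6 ± 18.4 CPM in WT and 37.1 ± 4.05 CPM in KO cells under control condition, and at 54.1 ± 6.15 and 38.8 ± 1.77 CPM under tunicamycin. The transcript thus was lower in KO cells under control condition (log2 fold change -0.71, SE 0.20, adjusted p = 0.0222), while the difference under tunicamycin did not pass the test (-0.48, SE 0.20, adjusted p = 0.134). WT control replicate 2 held 40.95 CPM, inside the range of the KO libraries (33.1 to 41.2 CPM). The call under control condition ended without WT control replicate 1 (adjusted p = 0.177) or 3 (0.0708), without KO control replicate 2 (0.0756) or 3 (0.124), and in a fit of those 6 libraries alone (0.0905). Under tunicamycin ARID1A passed the test without WT control replicate 2 (0.0434). Over the genes called KO against WT under tunicamycin, WT control replicate 2 scored -0.951, beside -0.928 and -0.946 in the other WT control libraries and 1.25 to 1.30 in the KO control libraries. Gene counts show neither the edited allele nor the protein.

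The first comparison asks what tunicamycin changed in WT cells. DDIT3, which encodes the stress transcription factor CHOP, rose from 19.3 ± 4.52 to 450.2 ± 25.6 CPM (log2 fold change 4.55, SE 0.17, adjusted p = 3.07e-12). HSPA5, the main ER chaperone BiP, rose from 1566 ± 279 to 6562 ± 636 CPM (2.07, SE 0.11, adjusted p = 2.66e-10). Of the 10 sensors and transducers of the unfolded protein response 3 rose and none fell (4 rose adjusted over the list alone). XBP1 (ENSG00000100219) rose from 77.7 ± 14.2 to 153.5 ± 19.0 CPM (0.98, adjusted p = 0.000176), EIF2AK3, which encodes the sensor PERK, from 54.7 ± 14.2 to 118.8 ± 3.28 CPM (1.12, adjusted p = 0.000555), and ERN1 (ENSG00000178607), which encodes the sensor IRE1α, from 48.3 ± 12.6 to 82.9 ± 7.43 CPM (0.78, adjusted p = 0.00454). ATF4 gave 0.44 (adjusted p = 0.098, and 0.0165 without WT control replicate 2), and ATF6, ATF6B, MBTPS1, MBTPS2, EIF2S1 and TRAF2 did not pass the test either. The counts per gene do not separate spliced from unspliced XBP1.

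Among 23 targets of PERK and ATF4 in WT cells 19 rose and none fell (20 rose adjusted over the list alone), among them CHAC1, a glutathione-degrading enzyme, with 3.35, SESN2 with 2.54 and PPP1R15A, which restores translation by removing the phosphate from eIF2α, with 3.06. Of 24 ER chaperones and other ATF6 targets 14 rose and none fell, also when adjusted over the list alone, led by HERPUD1 (3.29), HSPA5, HYOU1 (1.18) and CRELD2 (1.85). Of 26 targets of IRE1 and XBP1 10 rose and 1 fell (14 and 2 adjusted over the list alone); FICD rose by 2.08, DNAJC3 by 1.31 and SEC24D by 1.06. Of 21 genes of ER-associated degradation 8 rose and none fell (10 rose adjusted over the list alone), with SEL1L at 1.78 and SELENOS at 1.19. Of 12 enzymes of serine and one-carbon metabolism 4 rose and none fell (5 adjusted over the list alone), with PSPH at 1.41. Of 17 genes of NF-kB signalling and inflammation 12 rose and none fell (16 rose adjusted over the list alone), including TNFAIP3 (2.96), an inhibitor of NF-kB, and the chemokine CXCL8, which went from 3.02 ± 0.7 to 45.9 ± 4.75 CPM. Of 16 epithelial markers 4 fell and none rose (5 fell adjusted over the list alone), led by ELF3 (-1.83) and CLDN4 (-0.65). Of 16 genes linked to ARID1A in other studies 4 rose and 1 fell, also adjusted over the list alone, led by the cystine transporter SLC7A11 (2.17), which is also among the PERK and ATF4 targets. With an estimated correlation the adjusted p of these lists were 4.97e-06, 0.000117, 0.0158, 0.00908, 0.00925, 0.00039, 0.0357 and 0.0158 in the order given, and 0.0193 for the sensors, so all of these calls held. Of 20 aminoacyl-tRNA synthetases 11 rose and none fell (12 adjusted over the list alone), with CARS1 at 1.2; that list passed with the preset correlation (adjusted p = 1.01e-08) but not with an estimated one (adjusted p = 0.0776 with an estimated correlation).

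In all, tunicamycin changed 1194 genes in WT cells, 640 higher and 554 lower, of which 455 changed at least 2-fold. The largest rises by the naming rule were in CXCL3, whose ratio was 58.2 (95% counting interval 15.7 to 487), ENSG00000269501 (log2 fold change 4.93), DDIT3, ENSG00000261114 (4.19), CXCL8 (3.93), KLF4 (3.90), STC2 (3.82), SLC6A9 (3.72), FAM43A (3.61) and ANKRD1 (3.43). The largest falls were in the pseudogene OR7E14P, whose control level was 29.3 times that under tunicamycin (9.73 to 144.7), in TET1 (-4.28), ENSG00000261512 (-3.27), LINC01106 (-3.02), the kinase gene SGK1 (-2.69), MEX3A (-2.66) and JADE2 (-2.65). The call of ENSG00000269501 ended without WT control replicate 1, 2 or 3 (adjusted p = 0.0808, 0.0711 and 0.117) or WT tunicamycin replicate 2 (0.375), and that of ENSG00000261512 without WT control replicate 2 or 3 (0.118 and 0.065) or WT tunicamycin replicate 1 or 2 (0.0897 and 0.11). The count fell to 776, 780 and 752 without WT tunicamycin replicate 1, 2 and 3, and to 761 in a fit of the 6 WT libraries alone.

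**Figure D2:**
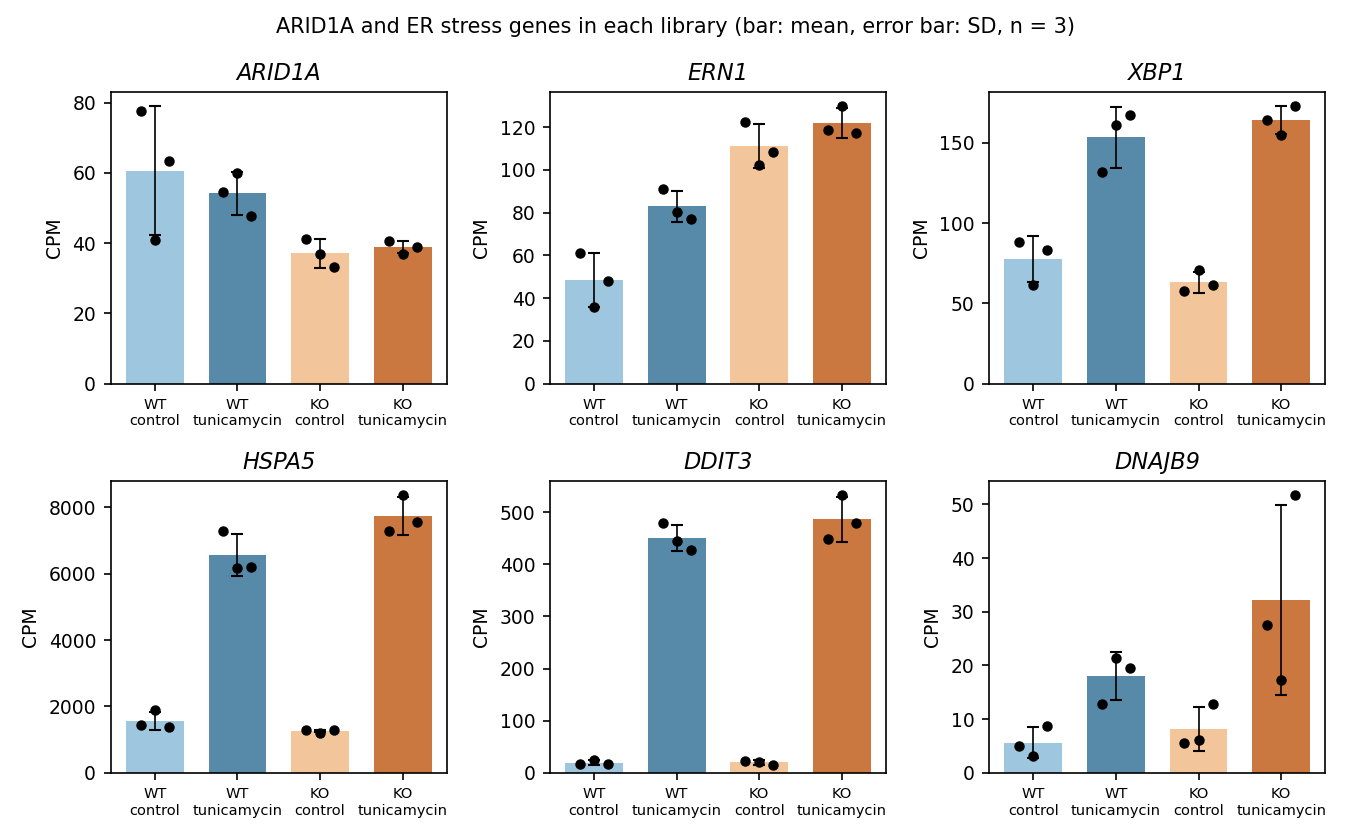
CPM (y axis) of ARID1A and 5 ER stress genes in the 4 groups (x axis); points are libraries, bars are means and error bars are SD, n = 3. DDIT3 goes from 19.3 to 450.2 CPM with tunicamycin in WT cells, and ERN1 in KO control cells (111.1 CPM) lies above its level in WT cells under tunicamycin (82.9 CPM).

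The second comparison asks what tunicamycin changed in KO cells. DDIT3 rose from 19.7 ± 4.28 to 486.3 ± 43.0 CPM (log2 fold change 4.62, SE 0.17, adjusted p = 1.22e-12) and HSPA5 from 1261 ± 41.0 to 7740.0 ± 564 CPM (2.62, SE 0.11, adjusted p = 7.39e-12). Of the 10 sensors and transducers 3 rose and none fell, also when adjusted over the list alone. XBP1 rose from 63.1 ± 6.60 to 164.1 ± 8.90 CPM (1.38, adjusted p = 3.25e-06), ATF4 from 540.1 ± 98.0 to 1338 ± 213 CPM (1.31, adjusted p = 3.78e-05) and EIF2AK3 from 79.2 ± 16.3 to 172.3 ± 22.9 CPM (1.12, adjusted p = 0.000379). ERN1 stood at 111.1 ± 10.3 CPM before and 122.1 ± 6.92 CPM under tunicamycin (0.14, SE 0.16, adjusted p = 0.684).

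Of the 23 targets of PERK and ATF4 20 rose and 1 fell in KO cells (21 and 1 adjusted over the list alone), with SESN2 at 3.05, CHAC1 at 3.46 and DDIT4, an inhibitor of mTORC1, at 2.67. Of the 24 ATF6 targets and chaperones 15 rose and 1 fell (16 and 2 adjusted over the list alone), with HERPUD1 at 2.73. Of the 26 targets of IRE1 and XBP1 10 rose and 1 fell (15 and 1 adjusted over the list alone), with FICD at 1.98 and SEC24D at 1.53. Of the 21 genes of ER-associated degradation 6 rose and none fell (9 rose adjusted over the list alone), with SEL1L at 1.35. Of the 12 enzymes of serine and one-carbon metabolism 8 rose and none fell (9 adjusted over the list alone), with GPT2 at 1.35 and SHMT2 at 0.82. Of the 17 genes of NF-kB signalling and inflammation 10 rose and none fell (13 adjusted over the list alone), with TNFAIP3 at 1.97 and CXCL8 at 2.89. Of 19 hypoxia targets 6 rose and 2 fell (6 and 3 adjusted over the list alone), led by VEGFA, the vascular growth factor, with 2.62 and NDRG1 with 1.2. With an estimated correlation the adjusted p of these lists were 2.60e-06, 0.000244, 0.0226, 0.0158, 0.00228, 0.0084 and 0.0226, and 0.0226 for the sensors. The aminoacyl-tRNA synthetases (11 rose and none fell of 20, 12 adjusted over the list alone; preset adjusted p = 2.96e-10) missed the threshold with adjusted p = 0.0579 with an estimated correlation. The ribosomal proteins (3 rose of 33, also over the list alone; preset adjusted p = 0.0317) did so with adjusted p = 0.164 with an estimated correlation, and with the preset one without KO control replicate 1 or 3 (adjusted p = 0.0524 and 0.0725) or KO tunicamycin replicate 3 (0.0586). The cell cycle list (1 rose and 3 fell of 33, 1 and 7 adjusted over the list alone; preset adjusted p = 0.0469) gave adjusted p = 0.106 with an estimated correlation. With the preset one its call ended without WT tunicamycin replicate 2 or 3 (adjusted p = 0.0546 and 0.0536), KO control replicate 1 or 2 (0.0524 and 0.0776) or KO tunicamycin replicate 3 (0.119).

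In all, 1479 genes changed with tunicamycin in KO cells, 832 higher and 647 lower, of which 514 changed at least 2-fold. With upper-quartile scaling the balance turned, with 700.0 higher and 755 lower. The largest rises were in DDIT3, RGS16, a regulator of G protein signalling (log2 fold change 4.11), ENSG00000261114 (3.88), STC2 (3.77), CYP1A1 (3.75), MAP1B (3.54), CHAC1 and FAM43A (3.35). RGS16 and CYP1A1 started at 0.477 ± 0.525 and 0.430 ± 0.413 CPM in KO control libraries, near the level of 3 counts, so the sizes of their rises rest on few counts. The largest falls in the order of the fitted fold changes were in the pseudogene CHCHD3P3 (at least 10.2-fold lower, against 3 counts in each library), PCDHA11 (-3.78), LINC01123 (-3.68), LRFN1 (-3.41) and AMER1 (-2.97). As CHCHD3P3 has only a bound, its place ahead of the others is not settled. Without KO control replicate 1 the calls of CHCHD3P3, PCDHA11, LINC01123, LRFN1 and AMER1 ended (adjusted p = 0.0513, 0.141, 0.0854, 0.0905 and 0.168). Without KO tunicamycin replicate 1 those of CHCHD3P3, PCDHA11, LINC01123 and AMER1 ended (0.0561, 0.101, 0.0617 and 0.0739), and without replicate 2 those of CHCHD3P3, PCDHA11 and AMER1 (0.0512, 0.103 and 0.0807). The call of CHCHD3P3 ended also without KO tunicamycin replicate 3 (0.0582), that of AMER1 without KO control replicate 2 (0.060), and that of PCDHA11 without KO control replicate 3 (0.0698), WT control replicate 3 (0.0525) or WT tunicamycin replicate 3 (0.0522). The count fell to 906 and 975 without KO control replicate 2 and 3.

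**Figure D3:**
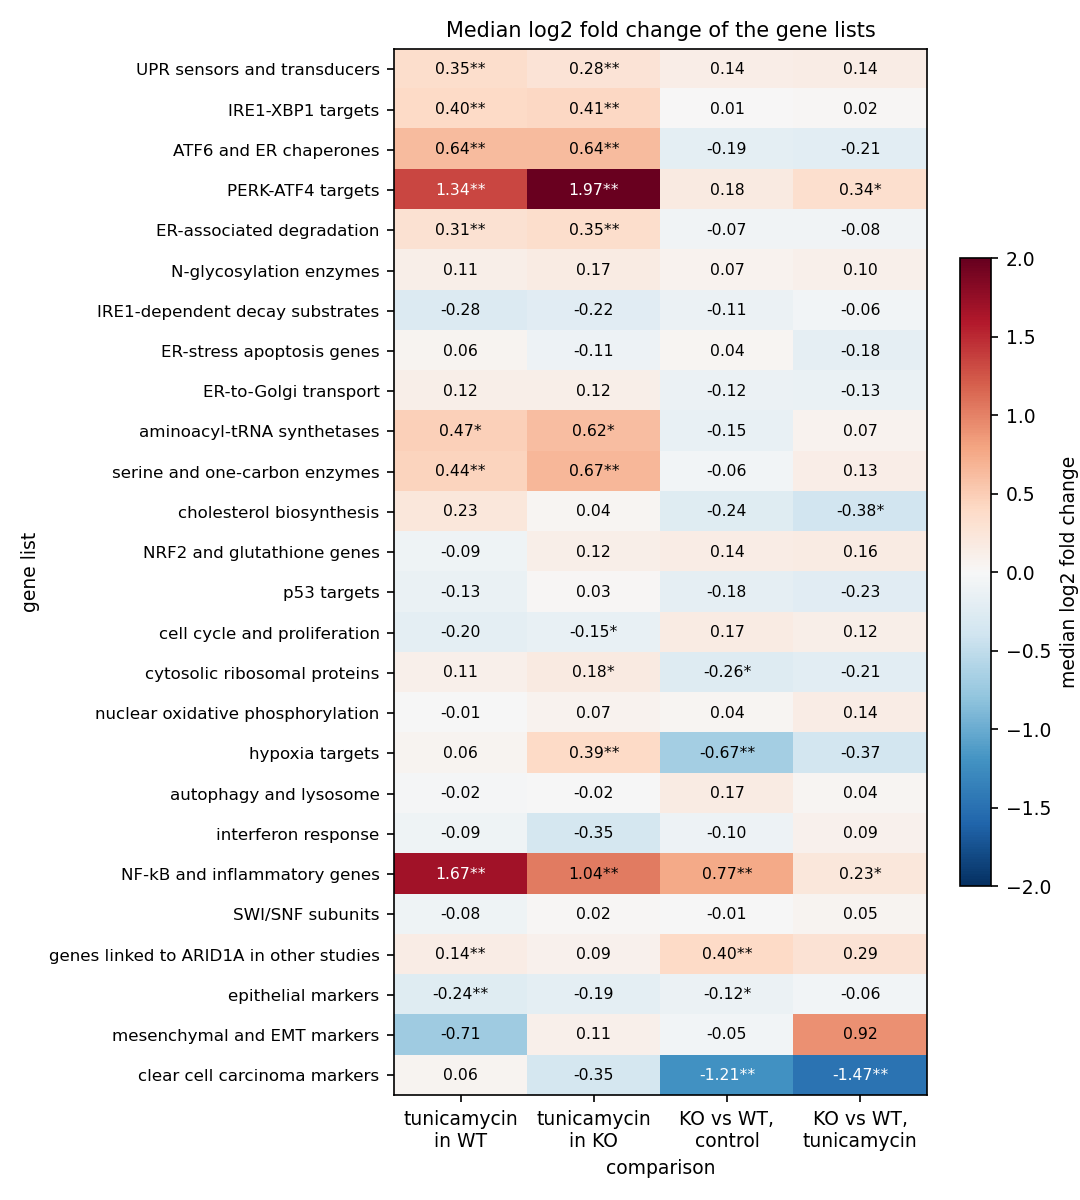
Median log2 fold change (colour and number) of 26 gene lists (y axis) in 4 comparisons (x axis). 2 asterisks mark a list with an adjusted p under 0.05 by camera both with the preset and with an estimated correlation, 1 asterisk with the preset one alone; the PERK and ATF4 targets have medians of 1.34 in WT and 1.97 in KO cells.

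The third comparison sets KO against WT cells under control condition. ERN1 was higher in KO cells, at 111.1 ± 10.3 CPM beside 48.3 ± 12.6 CPM (log2 fold change 1.2, SE 0.17, adjusted p = 3.26e-05), and ATF4 was lower, at 540.1 ± 98.0 beside 867.0 ± 176.0 CPM (-0.68, SE 0.15, adjusted p = 0.00644; without KO control replicate 3 adjusted p = 0.0583). XBP1 did not pass the test (-0.30, SE 0.15, adjusted p = 0.23, and 0.0432 without WT control replicate 2). The sensors and transducers as a list had 1 higher and 1 lower member of 10 (2 and 1 adjusted over the list alone) and an adjusted p of 0.443 by camera. With fry, which does not compare a list with other genes, this list passed with direction up (adjusted p = 0.00332). Of the 26 targets of IRE1 and XBP1 1 was higher and 3 lower, also over the list alone (list adjusted p = 0.926 by camera and 0.454 by fry). The higher ERN1 in KO cells thus came without a call of these targets as a list.

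Of 8 tested genes of the list of clear cell carcinoma markers 4 were lower in KO cells and none higher (5 lower adjusted over the list alone). SPP1, which encodes osteopontin, was lower by -1.74, FXYD2, a regulator of the sodium pump, by -4.94, GPC3 by -5.77, and MUC16, which carries the CA125 antigen, at least 20.4-fold. As fixed, the list also holds WT1, ESR1, PGR and MUC16, which are used to mark other ovarian carcinomas. Its call is thus not a measure of clear cell identity. Of 19 hypoxia targets 8 were lower and 1 higher (9 and 1 adjusted over the list alone), led by NDRG1 (-2.12), VEGFA (-1.89) and the carbonic anhydrase gene CA12 (-1.34). Of 17 genes of NF-kB signalling and inflammation 10 were higher and 1 lower, also adjusted over the list alone, led by BIRC3 (2.36), CXCL8 (3.01), CXCL1 (3.23) and TNF (1.92). Of 16 genes linked to ARID1A in other studies 7 were higher and none lower, also adjusted over the list alone, led by SLC7A11 (1.11), also a PERK and ATF4 target. These 4 lists passed with an estimated correlation as well (adjusted p = 0.0057, 0.0365, 0.0365 and 0.0392). The ribosomal proteins (7 lower and none higher of 33, 11 adjusted over the list alone; RPS24 -0.99, RPL11 -0.87) passed with the preset correlation (adjusted p = 0.0068) and not otherwise (adjusted p = 0.133 with an estimated correlation). So did the epithelial markers (2 higher and 6 lower of 16, 3 and 6 adjusted over the list alone; adjusted p = 0.0364, and 0.118 with an estimated correlation), with ST14, a membrane protease, at -2.79, MUC1 at -1.66, KRT19 at -0.66 and EPCAM at 0.60. With the preset correlation the call of the epithelial markers ended without WT control replicate 1 or 3 (adjusted p = 0.0575 and 0.0534), KO control replicate 1 or 2 (0.0822 and 0.0588) or KO tunicamycin replicate 1 or 2 (0.0508 and 0.0528).

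Of 30 enzymes of N-glycosylation 1 was higher and 3 were lower in KO cells (1 and 5 adjusted over the list alone; list adjusted p = 0.983). STT3A, a catalytic subunit of the oligosaccharyltransferase, was lower by -1.22, ALG11 by -0.96, and DPAGT1, the enzyme that tunicamycin inhibits, by -1.07 (26.9 ± 7.15 CPM in WT and 12.9 ± 2.40 CPM in KO cells, adjusted p = 0.00718; without WT control replicate 1 adjusted p = 0.0518). Among 26 SWI/SNF subunits 2 were higher and 2 lower, also adjusted over the list alone (list adjusted p = 0.964): DPF3 was at least 10.2-fold lower with no count in KO control libraries, ARID1A was lower, and SMARCA2 was higher by 0.77. The fourth, ARID2, was higher by 0.54, a call that ended without WT control replicate 2 or 3 (adjusted p = 0.0784 and 0.0682) or KO control replicate 2 or 3 (0.182 and 0.0511). Of 18 markers of other cell types only PTPRC, which encodes the leukocyte antigen CD45, had enough counts to be tested. It had no count in the WT libraries and 2.76 ± 1.36 CPM in KO control libraries (at least 5.21-fold higher, adjusted p = 0.00849).

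In all, 1777 genes differed between KO and WT cells under control condition, 701 higher and 1076 lower in KO, of which 931 differed at least 2-fold. The largest rises were in PSG8 (at least 22.9-fold), SRL (at least 19.8-fold), ENSG00000255372 (at least 13.5-fold), CSH1 (at least 11.9-fold) and TG (at least 11.8-fold), all with no count in the WT control libraries, then PSG1 (ratio 303.3, interval 83.6 to 2510), LGALS1 (log2 fold change 6.24), BRSK2 (ratio 83.5, interval 22.8 to 695), LAMA4 (5.84) and OSBPL5 (ratio 48.4, interval 16.3 to 237). PSG8, PSG1 and CSH1 belong to families of near-identical genes among which reads are hard to assign. The largest falls were in MT1M (at least 78.0-fold), FXYD3 (ratio 818, interval 279.5 to 3969), MMP10 (at least 22.3-fold), PXDN (ratio 591.5, interval 163 to 4890), MUC16, KLK6 (at least 20.3-fold), HABP2 (ratio 634, interval 113 to 25090), S100P (ratio 613, interval 109.6 to 24260) and MIR205HG (ratio 603, interval 108 to 23840). MT1M too belongs to such a family. Bounds are against 3 counts in each library of the group, and intervals and bounds cover counting error only. The order follows the fitted fold changes, so the place of a gene given as a bound is not settled.

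Along the chromosomes, medians of 161 windows of 50 neighbouring genes were taken, and 12 lay beyond 0.243, the limit that random gene orders gave. Of these 10 were lower and 2 higher in KO cells. The last full window of chromosome 11 had a median of -0.915 (-0.888 under tunicamycin) and a window of chromosome 12 a median of 0.485 (0.473). The others were 3 windows of chromosome 10, 2 each of chromosomes 1 and 13, and 1 each of chromosomes 4, 11 and 14. Under tunicamycin 10 windows lay beyond 0.257, 8 of these 12 and the 2 windows of chromosome 18 (-0.334 and -0.352, and -0.209 and -0.128 under control condition). ARID1A itself lies in 1 of the 2 windows of chromosome 1 (median -0.265, and -0.147 under tunicamycin), and ARID2 in the window of chromosome 12. Other genes named in the text also lie in these 12 windows: RPL11 and SESN2 on chromosome 1, CXCL1 and CXCL8 on 4, ANKRD1, RPS24, NDUFB8 and HABP2 on 10, CARS1, FXYD2 and NNMT on 11, ALG11, NRAD1 and DNAJC3 on 13, and SEL1L on 14. HYOU1, ST14, STT3A, DPAGT1 and ARCN1 lie on chromosome 11 beyond its last full window, where 38 of 41 genes were below the median of all genes.

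The fourth comparison sets KO against WT cells under tunicamycin. ERN1 was higher in KO cells, at 122.1 ± 6.92 beside 82.9 ± 7.43 CPM (log2 fold change 0.56, SE 0.16, adjusted p = 0.0244). That call ended without WT tunicamycin replicate 2 (adjusted p = 0.0876) or 3 (0.101) and without KO tunicamycin replicate 1 (0.0526), 2 (0.0868) or 3 (0.0504). XBP1 (0.10, SE 0.14, adjusted p = 0.759) and ATF4 (0.19, SE 0.15, adjusted p = 0.514) did not pass the test. Of the 10 sensors and transducers 1 was higher and none lower (2 adjusted over the list alone). The list gave adjusted p = 0.275 by camera and passed with fry (0.00136, direction up). Of the 26 targets of IRE1 and XBP1 1 was higher and 4 lower (2 and 6 adjusted over the list alone, list adjusted p = 0.694 by camera and 0.32 by fry). Of the 8 clear cell carcinoma markers 5 were lower and none higher (6 adjusted over the list alone), with SPP1 at -1.85 and FXYD2 at -4.98, and this list passed with both correlations (adjusted p = 0.00214 with an estimated correlation).

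Of the 23 targets of PERK and ATF4 9 were higher and 2 lower in KO cells under tunicamycin (11 and 4 adjusted over the list alone), with NUPR1, a stress-induced chromatin protein, at 2.01, CHAC1 at 1.07, STC2 at 1.85 and ATF3 at 1.36. That list passed with the preset correlation (adjusted p = 0.000231) and gave adjusted p = 0.126 with an estimated correlation. Of 23 genes of cholesterol biosynthesis 8 were lower and 2 higher (11 and 2 adjusted over the list alone; adjusted p = 0.0361, 0.182 with an estimated correlation, and 0.0747 without WT tunicamycin replicate 3), with HMGCS1 at -0.90. Of the 17 genes of NF-kB signalling and inflammation 6 were higher and 2 lower (6 and 4 adjusted over the list alone; adjusted p = 0.0155, and 0.233 with an estimated correlation), with CXCL8 at 1.97 and CXCL1 at 1.84. Of the 19 hypoxia targets 2 were higher and 7 lower (3 and 8 adjusted over the list alone; adjusted p = 0.0946), with NDRG1 at -1.25.

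In all, 1901 genes differed under tunicamycin, 803 higher and 1098 lower in KO cells, of which 976 differed at least 2-fold. The largest rises were in ENSG00000255372 (at least 39.4-fold), LAMA4 (at least 37.2-fold), PSG8 (at least 23.2-fold), PSG1 (ratio 569.6, interval 102 to 22540) and SRL (at least 12.01-fold). The largest falls were in S100P (at least 77.0-fold), S100A9 (at least 45.7-fold), LINC03033 (at least 39.2-fold), NRAD1 (at least 32.9-fold), PXDN (ratio 989, interval 177 to 39100) and FXYD3 (ratio 853, interval 236 to 7049). Here too the order follows the fitted fold changes, and the place of a gene given as a bound is not settled. Across the 13588 genes the KO against WT log2 fold changes under the 2 conditions had Pearson r = 0.675 and Spearman rho = 0.532, a correlation across genes, which are not independent replicates. Without a filter on low counts that r was 0.266. Called in both were 424 genes higher (41.4 by chance) and 710.0 lower (86.9 by chance), while 4 were called in opposite directions.

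The fifth comparison asks whether the response to tunicamycin differed between KO and WT cells. Across genes the 2 responses had Pearson r = 0.385 and Spearman rho = 0.467, and r was 0.103 without a filter on low counts and 0.640 for genes with at least 50 counts in 3 libraries. Called in both genotypes were 411 genes higher (39.2 by chance) and 262 lower (26.4 by chance), with 3 in opposite directions, and 92.3% of the genes called in either genotype moved the same way in both. The test of the difference itself called 17 genes, 14 with a more positive response in KO cells and 3 with a more negative one, while 1048 had an unadjusted p under 0.05. VEGFA rose from 21.2 ± 0.8 to 130.8 ± 7.63 CPM in KO and from 78.9 ± 6.12 to 168.5 ± 11.5 CPM in WT cells (difference in log2 fold change 1.53, SE 0.18, adjusted p = 0.000857). TRIB3, a pseudokinase induced by ATF4 and CHOP, rose from 44.6 ± 9.10 to 350.7 ± 14.2 CPM in KO and from 181.1 ± 47.4 to 457.5 ± 29.8 CPM in WT cells (1.64, SE 0.24, adjusted p = 0.00451). TNFAIP3 rose less in KO cells (-1.0, SE 0.16, adjusted p = 0.00768), and SUSD6 rose from 19.97 ± 5.0 to 52.4 ± 3.38 CPM in WT cells and stood at 10.8 ± 1.80 and 5.41 ± 0.521 CPM in KO cells (-2.37, SE 0.35, adjusted p = 0.00451). None of the 10 sensors and transducers passed this test over all genes and 1 did adjusted over the list alone. ERN1 gave -0.64 (SE 0.23, adjusted p = 0.496), XBP1 0.40 (SE 0.21, adjusted p = 0.692) and ATF4 0.87 (SE 0.22, adjusted p = 0.241). None of the 26 targets of IRE1 and XBP1 passed it, over all genes or over the list alone (list adjusted p = 0.931 by camera). The count was 44 without WT control replicate 2, 10 and 11 without WT tunicamycin replicate 1 and 2, 83 with no filter on low counts and 64 with DESeq2. Without WT control replicate 2 the response in KO cells was more positive for 28 genes and more negative for 16, so the balance of 14 and 3 is not stable.

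**Figure D4:**
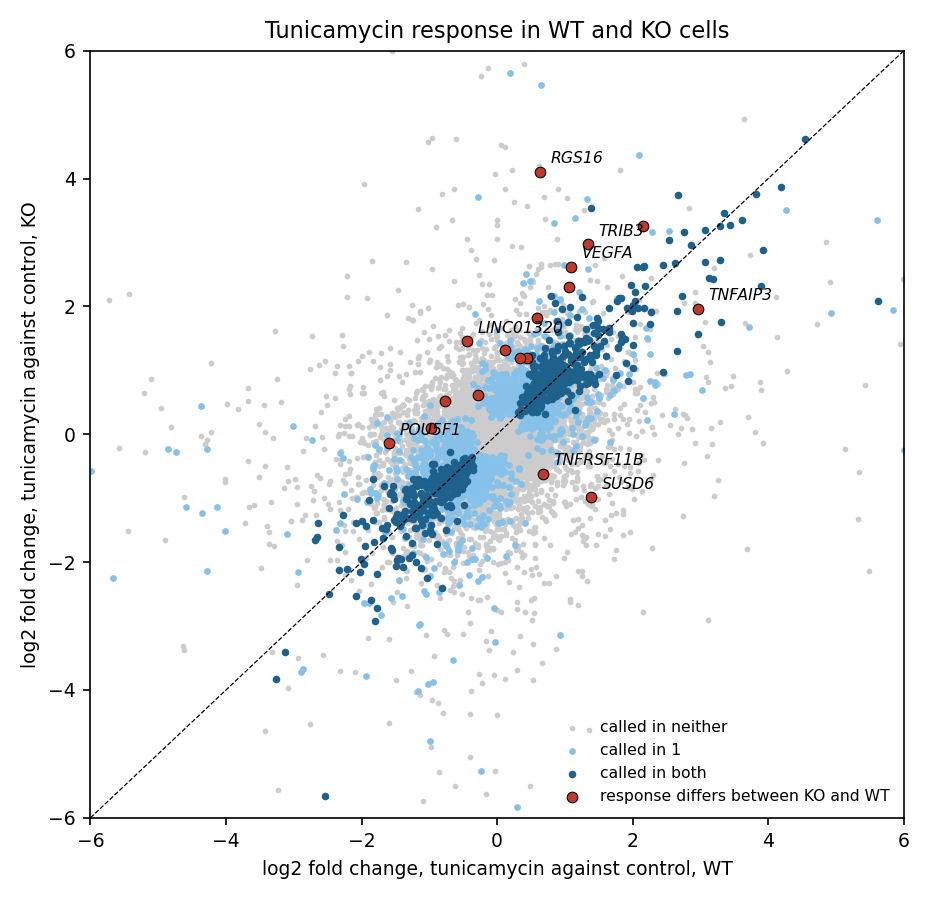
Log2 fold change with tunicamycin in WT (x axis) and KO cells (y axis) for the tested genes; each point is a gene, coloured by the comparisons in which it was called, and 37 genes lie outside the axes. The 17 red points are the genes whose response differed between the genotypes, and the dashed line marks equal responses.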

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

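The test without 4 libraries was chosen after the result was seen. The test of the difference between the tunicamycin responses of KO and WT cells brought 17 genes and 4 gene lists here. The response was more positive in KO cells (difference of log2 fold changes) for RGS16 (3.47), LINC01320 (1.90), TRIB3 (1.64), VEGFA (1.53), POU5F1 (1.46), PPP1R10 (1.29), C6orf132 (1.26), PMEPA1 (1.23), LIMS4 (1.21), GADD45A (1.11), NNMT (1.08), MFSD12 (0.90), NDRG1 (0.86) and GDF15 (0.75). It was more negative for TNFAIP3 (-1.0), TNFRSF11B (-1.30) and SUSD6 (-2.37). LIMS4 has a near-identical copy, among which reads are hard to assign.

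Many of these genes differed between the genotypes before treatment. RGS16 stood at 19.3 ± 0.693 CPM in WT and 0.477 ± 0.525 CPM in KO control libraries, and LINC01320 at 105.8 ± 7.73 and 5.98 ± 1.95 CPM. A larger log2 response in KO cells thus started from a lower level for these 2 genes and for VEGFA, TRIB3, NDRG1, PMEPA1 and C6orf132. GDF15, a secreted stress cytokine, started higher in KO cells (1371 ± 46.1 beside 845.5 ± 49.8 CPM) and also rose more. NNMT fell in WT cells (-0.97) and its change in KO cells was 0.10 (adjusted p = 0.722).

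By the preset correlation the interaction passed for the NF-kB list (adjusted p = 6.34e-11), the PERK and ATF4 targets (adjusted p = 0.00473), cholesterol biosynthesis (adjusted p = 0.038) and the hypoxia targets (adjusted p = 0.038). With an estimated correlation these 4 lists gave adjusted p = 0.113, 0.216, 0.222 and 0.216. With fry, which does not compare a list with other genes, the NF-kB list passed (adjusted p = 0.0357) and the other 3 did not (0.0669 each). Of the NF-kB list 1 member of 17 was lower (6 adjusted over the list alone), of the PERK and ATF4 targets 1 of 23 was higher (6), of the cholesterol list none of 23 (1 lower over the list alone) and of the hypoxia targets 2 of 19 were higher (3). With the preset correlation the call of the PERK and ATF4 targets ended without WT control replicate 1 (adjusted p = 0.0614). That of the cholesterol list ended without WT tunicamycin replicate 2 or 3 (adjusted p = 0.0502 and 0.191) or KO control replicate 2 or 3 (0.0866 and 0.0567). That of the hypoxia targets ended without WT control replicate 1 or 3 (adjusted p = 0.169 and 0.0758), WT tunicamycin replicate 1 or 3 (0.0551 and 0.205), KO control replicate 1 or 2 (0.141 and 0.101) or KO tunicamycin replicate 1 (0.193).

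Without any 1 library no gene changed sign, and the smallest share of its log2 size that a gene kept was 0.8 (NNMT without WT control replicate 2). The genes were called against the spread of these same libraries, which a gene resting on 1 library would seldom pass. This test thus says little on a single control library as the source. Calls were less stable than sizes. SUSD6, TRIB3, VEGFA, TNFAIP3, PMEPA1, TNFRSF11B, PPP1R10 and LINC01320 were called in 12 of the 12 fits that left out a library. GDF15 was called in 11, GADD45A and POU5F1 in 10, RGS16 in 8, LIMS4 in 7, NNMT in 5, C6orf132 and NDRG1 in 4 and MFSD12 in 2, with adjusted p of up to 0.058, 0.0609, 0.0632, 0.0716, 0.0821, 0.109, 0.204, 0.0811 and 0.245. The count was 44 without WT control replicate 2, and 10 and 11 without WT tunicamycin replicate 1 and 2.

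Without the 4 libraries that deviate most in their group along the within-group axis (described below) 16 of the 17 genes were still called. The count over all genes went from 17 to 69. MFSD12 was the exception. The libraries left out were picked as the most extreme, so leaving them out lowers the spread within groups along the axis. A gene resting on these libraries would also seldom have been called at first. The 16 kept calls thus say little on these libraries as the source. The libraries kept also differ along the axis, so the axis itself was not removed. With the axis score as a covariate 17 were called, but the scores are centred within each group and come from the same counts, so this test says nothing. In 100 of the 200 possible exchanges of KO and WT libraries within each treatment, 4 gave at least 17 genes, the real one included. Most of these exchanges mix KO and WT libraries within a group, so the difference between genotypes enters the spread within groups, and this share does not settle whether chance gave the 17. The highest other gave 338, and the next gave 158 and 51. The exchanges with 338 and 158 keep the 6 tunicamycin libraries in their genotype and exchange 4 of the 6 control libraries. In such an exchange the contrast holds the KO against WT difference under tunicamycin, which by itself called 1901 genes. Counts far above 17 can thus come from the difference between genotypes and are no sign of another structure of the samples. Of the other exchanges of this make-up 2 gave 0, and 1 with all labels mirrored gave 1. A difference in the response that goes with the genotype stays among the open explanations. Over all tested genes the difference had Spearman rho = 0.141 with GC content and -0.068 with transcript length, which leaves GC content open for these genes. Reads shared between copies were not tested.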

How the results depend on the processing

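The axis covariate and the fit of 2 libraries per group were chosen after the data were seen. Counts are in the order tunicamycin in WT, tunicamycin in KO, KO against WT under control condition, KO against WT under tunicamycin, and interaction; the reported counts are 1194, 1479, 1777, 1901 and 17.

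With RLE scaling the counts were 1188, 1450.0, 1762, 1909 and 16, and with upper-quartile factors 1198, 1455, 1760.0, 1890.0 and 15. Upper-quartile factors lowered the share of rises among calls of tunicamycin in KO cells from 56.3% (832 higher, 647 lower) to 48.1% (700.0 higher, 755 lower), and no scaling moved the median of all genes by over 0.1. With no filter the interaction count was 83 and the 2 correlations fell from 0.385 and 0.675 to 0.103 and 0.266. With at least 50 counts in 3 libraries they were 0.640 and 0.833. DESeq2 called 64 genes in the interaction and limma-voom 14. Of the reported interaction genes DESeq2 called all, while limma-voom did not call RGS16, GADD45A, MFSD12, NNMT and C6orf132. The fit of the 2 groups compared gave 761 for tunicamycin in WT.

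An adjusted p under 0.01 left 594, 717, 1087, 1119 and 10 genes. Tested against a fold change of 1.5, 216, 229, 644, 666 and 1 remained past the threshold. The axis covariate gave 2346, 2682, 2896, 3046 and 335, but it is built from the same counts, so these higher numbers are no evidence. With 2 libraries per group the interaction count was 69.

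The labels share replicate numbers, but of 18 pairs with the same number 1 had a correlation over 0.1 (range -0.168 to 0.22), and 5 of 12 libraries were closest to their own number, so the groups were not treated as paired. With a replicate block the counts were 1235, 1491, 1750.0, 1933 and 21. Of the list results 133 stayed on their side of the threshold, 1 gained a call and 1 lost it. For the named genes 311 results stayed and 2 lost their call.

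Leaving out 1 library gave 752 to 1282, 906 to 2004, 1249 to 1785, 1395 to 2431 and 10 to 44 genes. The correlation of the tunicamycin responses was 0.294 to 0.336 and that of the KO against WT changes 0.575 to 0.624. Both ranges lie below the values of all libraries (0.385 and 0.675). The filter was run anew in each of these fits, and its demand follows the smallest group, so genes of lower count can enter. The ranges thus mix a change of the filter with the loss of a library.

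With an estimated correlation 122 of 135 list results stayed on their side of the threshold and 13 lost their call. With fry, which does not compare a list with other genes, 90 stayed, 42 gained a call and 3 lost it, the interaction of the PERK and ATF4, cholesterol and hypoxia lists. Over the fits that left out a library 1576 list results stayed, 17 gained a call and 27 lost it. For the named genes over those fits 3612 results stayed, 19 gained a call and 125 lost it.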

Other observations

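The direction test of 600 genes, the genes beyond the last windows and the 0.7 shift of the window self-test were chosen after the result was seen. The list results of this and the next paragraph did not pass the test with all libraries and the preset correlation. With fry, which does not compare a list with other genes, those of ER-stress apoptosis, N-glycosylation and IRE1-dependent decay passed in both genotypes, and those of decay, ER-to-Golgi transport, cell cycle, and autophagy and lysosome between KO and WT cells under control condition. Of 17 genes of ER-stress apoptosis 3 rose and 1 fell with tunicamycin in WT cells and 4 rose and 2 fell in KO cells, and PMAIP1, which encodes the death factor NOXA, rose by 2.17 and 2.63. The list itself gave adjusted p of 0.168 and 0.478. Of 17 p53 targets 2 rose and none fell in WT and 3 rose and 1 fell in KO cells (adjusted p = 0.775 and 0.688), with GDF15 at 0.44 and 1.19. Of 30 N-glycosylation enzymes 1 rose in WT and 4 in KO cells (adjusted p = 0.151 and 0.108), with ALG2 at 0.80 and 0.73. Of 7 substrates of IRE1-dependent decay 1 fell in each genotype (adjusted p = 0.25 and 0.434).

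Between KO and WT cells under control condition, of 19 NRF2 and glutathione genes 3 were higher and 5 lower (adjusted p = 0.983), with TXNRD1 at 1.13. Of 33 cell cycle genes 6 were higher and 1 lower (adjusted p = 0.102, but 0.0285 without WT control replicate 2 and 0.0393 without KO control replicate 3), with CDC20 at 1.2 and MKI67 at -0.90. Of 21 autophagy and lysosome genes 2 were higher and 2 lower (adjusted p = 0.399), with NPC1 at 1.18 and LAMP2 at -0.81. Of 24 genes of ER-to-Golgi transport 3 were lower (adjusted p = 0.179), with TMED10 at -0.76 and ARCN1 at -1.19. Of 7 substrates of IRE1-dependent decay 2 were lower (adjusted p = 0.052, but 0.0488 without WT control replicate 1 and 0.0476 without WT tunicamycin replicate 3), COL6A1 by -1.25 and SCARA3 by -2.45. Of 30 genes of oxidative phosphorylation 2 were lower (adjusted p = 0.964), with NDUFB8 at -0.61. Of 13 interferon genes 1 was higher (adjusted p = 0.926), and of 8 mesenchymal markers none was called (adjusted p = 0.696).

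KO against WT changes ran in blocks along chromosomes. Under control condition 12 of 161 windows lay beyond the limit of 0.243, 12 of 12 had the same sign under tunicamycin, 8 were beyond the limit under both conditions (of 10 under tunicamycin, where the other 2 were the windows of chromosome 18), and window medians of the 2 conditions had Pearson r = 0.781. The 12 windows met the prediction for a shift of whole chromosome stretches, as a copy number difference between the KO and WT cells would give. That prediction asked only for the same sign under tunicamycin, and not all windows kept their size. From control to tunicamycin the first window of chromosome 11 went from -0.275 to -0.056 and that of chromosome 4 from 0.341 to 0.079. Those of chromosome 1 went from -0.265 to -0.147 and from -0.263 to -0.215, all inside the tunicamycin limit of 0.257. With tunicamycin as the contrast 0 windows lay beyond in WT and 1 in KO cells. Without the called genes a share of 0.417 of the 12 windows (5) lay beyond, but leaving out called genes shrinks the median of a true shift too, so this test says nothing on a few strongly changed genes in each stretch. Under tunicamycin 77.3% of the 600 genes in these windows moved in the direction of their window. In 8 of the 12 windows the share passed 66%, the limit for chance. The windows were picked by their medians under control condition, which a few strong genes hardly move. The KO against WT changes of all tested genes under the 2 conditions had Pearson r = 0.675. High shares can thus arise from this choice without a regional shift, so the direction test does not decide on such genes either. On chromosomes 10, 11, 13 and 14 the last full window was among the 12. The genes beyond it, which no window holds, were below the median of all genes in 38 of 41 cases on chromosome 11 (median -0.867), 37 of 39 on chromosome 10 (-0.487) and 39 of 46 on chromosome 14 (-0.419), but in 7 of 14 on chromosome 13 (-0.022). On chromosomes 1, 4 and 12, whose windows are not at their end, it was 23 of 49 (0.111), 10 of 40 (0.202) and 11 of 25 (0.04). A copy number or clonal difference between the KO and WT cells is a hypothesis that may account for part of these changes, and regional regulation after loss of ARID1A stays open, since expression does not separate them. How the KO cells were made and how many clones they come from is not stated.

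The first component of the within-group deviations (23.3% of that variance) gave an axis. In each group the library with the largest absolute score was taken, so every group has 1 by construction. They were WT control replicate 2 (score 58.24), WT tunicamycin replicate 1 (20.87), KO control replicate 1 (27.2) and KO tunicamycin replicate 2 (31.17). These libraries also have the 4 lowest totals. Their scores had the same sign, but the score in WT control was the largest. The deviations of these libraries from their group means correlated only weakly, with r of 0.08 to 0.22 between pairs. In these 4, TMSB4X stood at 113.5 CPM beside 529.9 CPM in the other 8, CCN1 at 119.0 beside 406.2 and PLAU at 32.2 beside 148.7. Genes without a name and pseudogenes were also among the largest weights. TMSB4XP8 stood at 6.8 beside 36.1 CPM and RPL3P4 at 46.7 beside 145.9, while RPS27P3 went the other way (35.5 beside 8.4). Whether reads shared between copies play a part was not tested. After all libraries were thinned to the smallest total a share of 0.98 of the separation stayed, which argues against the count total by itself. Whether what lowered these totals also made the axis was not tested, and thinning cannot show it. The Spearman rho of the gene weights was 0.18 with GC content and -0.01 with transcript length (values for 97.3% of genes). The bound set beforehand for no bias asked for both values to lie under 0.1 in size. That for length did, while that for GC content lies between this bound and the one set for bias. The joint test thus cannot tell GC content or length bias apart from other sources. The labels give no batch, and no biological explanation was tested since the axis crosses all 4 groups.

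For tunicamycin in WT cells 1 of the 10 splits of the 6 libraries, the real one, gave 1194 genes, and the highest other gave 1. For tunicamycin in KO cells it was 1 split with 1479 and the highest other 0, for KO against WT under control condition 1 split with 1777 and the highest other 0, and for KO against WT under tunicamycin 1 split with 1901 and the highest other 0. The 10 splits are too few for a share under 0.05.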
